A study of Mus musculus with 30 samples.

How the data were processed

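Poly(A)-selected RNA was sequenced from 5 lines of the mouse insulinoma cell line βTC3, which makes insulin and came from a mouse pancreatic islet tumour. Per the labels, the lines carried doxycycline-inducible constructs in piggyBac plasmids: a control, ALK7 (the type I receptor encoded by Acvr1c), a dominant-negative form of ALK7 (ALK7-DN), a single hairpin against ALK7 (sh2) and a pair of hairpins (sh1/2). The control, ALK7 and ALK7-DN lines shared one plasmid backbone, and both hairpin lines another, for which no line without a hairpin was among the samples. All cells received 1 µg/ml doxycycline (DOX) for 24 hours, alone or with 50 ng/ml activin B for 24 hours, so that 30 libraries formed 10 groups of 3. The labels gave batch 1 for 24 libraries and batch 2 for 6, namely the ALK7-DN libraries with activin B and the sh2 libraries with DOX alone. In these 2 lines batch and treatment coincided.

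Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17, adapters were trimmed with cutadapt 1.4.2, reads were aligned to mm10 with HISAT2, and featureCounts 1.4.4 counted reads per gene. The HISAT2 version, the strand setting of the counting and the handling of reads that match several places were not given in the sources used here. Genes with near-identical copies or pseudogenes, such as Gapdh, Ldha, Aldoa, Pgk1-rs7, Tpt1-ps6 and Rpl31-ps8, are therefore reported as uncertain. The deposited count tables held integer read counts per gene for 39017 genes. All 30 count columns of the series table were identical to the files of the single samples. The authors also deposited a normalized expression table of 10580 genes in log2 CPM (library-scaled counts), made with edgeR per the submitters' processing notes. Its symbols matched 10058 of the genes tested here. Of the matched values, 99.7% lay within 0.15 of log2 CPM recomputed from the counts, with a median difference of -0.0450. All 30 columns of each table were assigned to a sample and 0 columns were left unassigned.

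Library totals ran from 18904884 to 34740789 counts. Between replicates the lowest chi-square per degree of freedom was 8.25, so replicates differed by more than counting error. The replicates were wells of one line, and p-values therefore measured only the spread between these samples, which may be technical.

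Differences were tested on the counts with edgeR 4.0.16 in R 4.3.3: the low-count filter filterByExpr, which left 15627 genes, TMM normalization, a model of 10 group means fitted to all 30 libraries, and the quasi-likelihood F test. The Benjamini-Hochberg adjusted p threshold was 0.05, and every adjusted p of a gene below comes from this test unless another tool is named. Values are log2 fold changes with standard errors (SE) and mean CPM with standard deviations (SD), n = 3 libraries per group. There were 14 contrasts: activin B against DOX alone within each of the 5 lines, the difference of that response between each other line and the control (interaction terms), each line against the control under DOX alone, and sh2 against the control with activin B, the only arm where these lines share a batch. The log2 CPM used for plots and library trends had a pseudocount of 2.

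There were 24 gene lists with 603 genes, of which 23 had measured members. The list of mitochondrially encoded genes had 0 counts in every library. The lists covered activin and TGF-β receptors, ligands and SMADs, SMAD2/3 targets, BMP and SMAD1/5 targets, beta cell identity, secretory granules, other islet hormone cells, progenitor genes, exocrine and duct cells, stromal, endothelial and immune cells, epithelial-mesenchymal transition, extracellular matrix, apoptosis, p53 targets, the unfolded protein response, G1/S, G2/M, cyclins with their kinases and inhibitors, interferon response, cholesterol synthesis, fatty acid metabolism, glycolysis, calcium and cAMP early genes, and host genes linked to SV40 T antigen. Members that rose or fell were counted over all genes tested and again adjusted over the list alone. Whole lists were tested against all other genes with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The fry test stood beside them.

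The design, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule named Acvr1c, Acvr1b, Tgfbr1, Acvr2a, Acvr2b, Smad2, Smad3, Smad4, Smad7 and Inhbb; up to 10 genes per direction (5 in the interactions and the sh2 contrasts against the control) with the largest log2 fold change among genes past the test with a mean of at least 2 CPM, a regular symbol and, except in interactions, no overlap between the libraries of the groups compared; the 4 members of each list with the smallest p; and up to 15 genes called in one direction in all 5 activin B contrasts. Of the first group, Inhbb did not pass the low-count filter.

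Same-numbered libraries of the paired arms of a line deviated together from their group means in the control (correlations 0.58, 0.60 and 0.18), ALK7 (0.33, 0.38 and 0.28), ALK7-DN (0.56, 0.11 and 0.39) and sh1/2 lines (0.38, 0.32 and 0.11), each over 0.1. The pairing comes from this check of the data, as the labels give only replicate numbers. A fit with the replicate number as a block was among the alternatives. The others were no filter, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-trend on the deposited table, a fit of only the groups compared, leaving out each library in turn, and a batch term that assumes equal responses of the hairpin lines. After the data were seen, further fits were added: removal of each library's trend with transcript GC content (smoothing span 0.3), or with GC content and length, for the 15453 genes (98.9%) with these properties; a block within each line, with and without the GC correction; and leaving out the 3 libraries whose gene-wise deviations correlated with GC content below -0.5 (Spearman), which leaves 1 library in the sh1/2 DOX arm.

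Some genes are not reported here. They stayed in the fits, the counts of calls and the list tests and were left out of the counts of gene values across alternative settings.

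The tests were checked on simulated counts with 50 genes changed at each size. For activin B in control cells, 38%, 78%, 80% and 88% of genes changed 1.25-, 1.5-, 2- and 4-fold were called, with 5 unchanged genes called. For the difference between ALK7 and control cells the shares were 22%, 60%, 78% and 78%, with 4 unchanged genes called. Where libraries carried the real GC trends and no gene was changed, the uncorrected test called 1380 genes for activin B in sh1/2 cells and the GC-corrected test called 0. For the difference between sh1/2 and control cells both tests called 0 genes in that simulation. Camera called the 1 changed list and 0 others. The simulated genes were drawn independently, so this does not check the preset correlation for lists whose genes vary together.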

Results

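The transcriptomes of 5 βTC3 lines, an insulin-producing mouse tumour cell line, were measured by poly(A) RNA sequencing. Cells had received doxycycline (DOX) for 24 hours, alone or together with activin B. Activin B is a ligand of the TGF-β family that can signal through the type I receptor ALK7. The lines carried a control construct, ALK7, a dominant-negative ALK7 (ALK7-DN), a single hairpin against ALK7 (sh2) or a pair of hairpins (sh1/2). Each of the 10 groups had 3 libraries. Library totals ran from 18904884 counts in sh1/2 DOX replicate 3 to 34740789 in control activin B replicate 1. The low-count filter kept 15627 genes. On a principal component analysis the first component held 23.8% of the variance and the second 15.6%. The libraries with activin B lay on one side of the first component and those with DOX alone on the other, in all 5 lines.

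**Figure D1:**
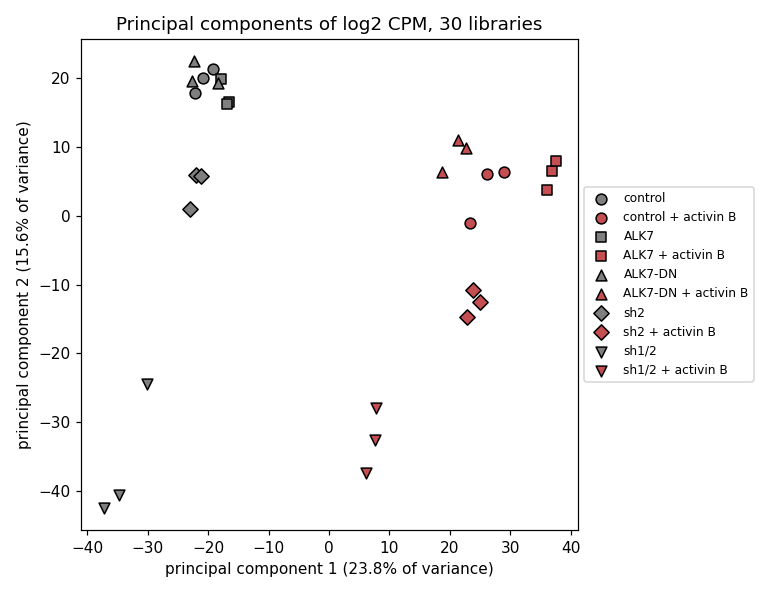
Principal component scores of the 30 libraries from log2 CPM, with the first component (23.8% of the variance) on the x axis and the second (15.6%) on the y axis. Colour gives the treatment and shape the line, and each point is 1 library; the treatments separate along the x axis.

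The first comparison asked whether the lines differed in the targeted gene. Acvr1c (mm10 chromosome 2, 58267453 to 58357895, minus strand, protein-coding), which encodes ALK7, stood at 165 ± 6.34 CPM (SD, n = 3) in control cells under DOX alone. It was lower in both hairpin lines, at 68.5 ± 12.8 CPM in sh2 (log2 fold change -1.27 ± 0.11 SE, adjusted p = 1.05e-08, edgeR quasi-likelihood test) and 55.3 ± 8.0 CPM in sh1/2 (-1.58 ± 0.11, adjusted p = 4.16e-11). With activin B, sh2 remained below the control within one batch, at 42.7 ± 1.79 against 101 ± 8.05 CPM (-1.24 ± 0.11, adjusted p = 1.87e-08). The line labelled ALK7 had 154 ± 11 CPM (-0.10 ± 0.10, adjusted p = 0.754) and the line labelled ALK7-DN 161 ± 7.50 CPM (-0.03 ± 0.10, adjusted p = 0.984). Neither expression construct was therefore visible in the Acvr1c counts, and both lines are named below as their labels give them. Smad2 (chromosome 18, 76241580 to 76310963, plus strand), a receptor-activated signal transducer of activin, was also lower in the hairpin lines, by -0.45 ± 0.05 in sh1/2 and by -0.24 ± 0.05 in sh2 with activin B (adjusted p 4.01e-08 and 0.000781). The sh2 call of Smad2 ended when only the 6 libraries compared were fitted (-0.25, adjusted p = 0.0560). The receptor gene Acvr1b was counted in every line, at 27.4 ± 2.14 CPM in control and 34.1 ± 3.75 in sh1/2 cells under DOX alone. It was called higher in sh1/2 cells (0.32), a call that ended with only these groups fitted (0.33, adjusted p = 0.0790). With activin B it stood at 46.5 ± 1.01 CPM in sh1/2 and 30.9 ± 3.04 in control cells, a pair that was not among the contrasts.

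**Figure D2:**
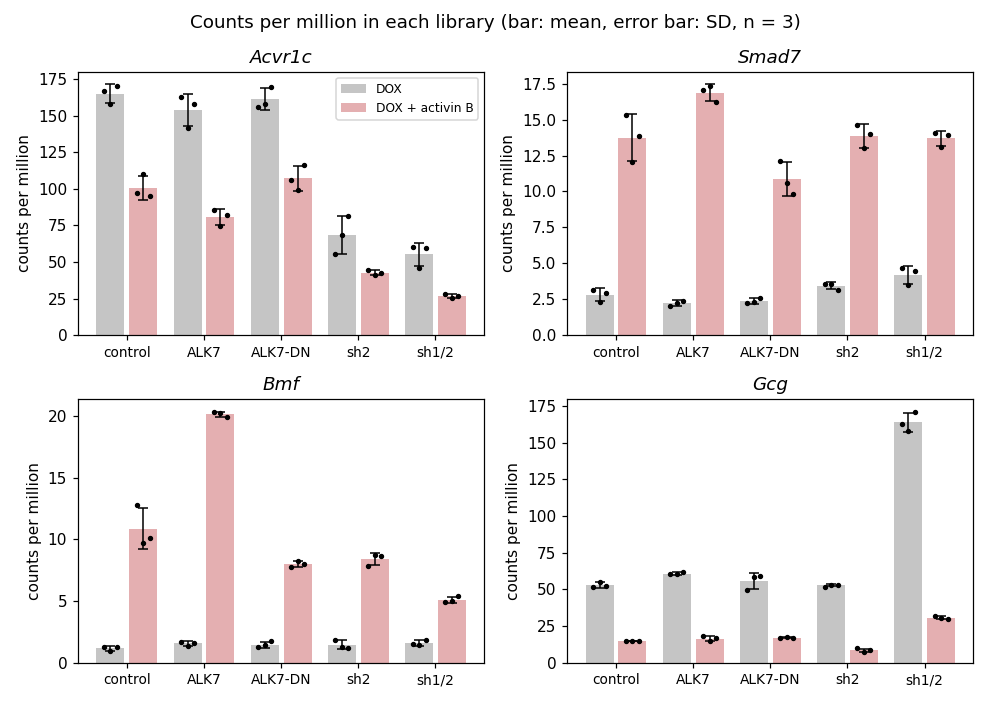
CPM of Acvr1c, Smad7, Bmf and Gcg in the 5 lines (linear y axis from 0), as bars of the mean with SD (n = 3) and 1 point per library, grey for DOX alone and red for DOX with activin B. Acvr1c fell from 165 to 101 CPM with activin B in control cells, Smad7 rose from 2.81 to 13.7, Bmf rose from 1.17 to 10.9 and Gcg fell from 52.8 to 14.5.

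The next comparison asked what activin B does in control cells. Activin B raised negative-feedback genes of the TGF-β pathway: Smad7 (chromosome 18, 75367529 to 75395935, plus strand), an inhibitory SMAD, rose from 2.81 ± 0.456 to 13.7 ± 1.63 CPM (log2 fold change 2.30 ± 0.12 SE, adjusted p = 2.83e-13). The pseudoreceptor Bambi rose by 1.76 ± 0.06 and the SMAD corepressor Skil by 1.84 ± 0.08. In contrast, Acvr1c fell by 0.71 ± 0.10 (adjusted p = 1.14e-05) and Smad3, which carries the signal to the nucleus, fell by 1.14 ± 0.09 (adjusted p = 2.94e-10). Large increases, here and below among genes with a mean of at least 2 CPM, were of Prr5l, which binds the kinase complex mTORC2 (6.24 ± 0.24, from 0.159 to 12.7 CPM), the matrix protein Spon2 (4.55 ± 0.18), the junction molecule Jam2 (4.47 ± 0.13), the latent TGF-β binding protein Ltbp2 (3.92 ± 0.22) and angiotensinogen, Agt (3.81 ± 0.21). Fam210b, a mitochondrial membrane protein, had the smallest p of all genes with 552 ± 21.5 against 46.7 ± 0.269 CPM (3.56 ± 0.05, adjusted p = 6.91e-25). Large decreases were of the opioid precursor Pdyn, from 81.0 ± 1.35 to 11.5 ± 0.520 CPM (-2.81 ± 0.13). They included the complement component C1qa (-2.45 ± 0.16), carboxypeptidase N subunit Cpn1 (-2.28 ± 0.14), Wfdc16 (-2.26 ± 0.18) and the homeobox gene Gbx2 (-2.21 ± 0.20).

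Among the SMAD2/3 targets in control cells, 15 of 30 measured genes rose and 1 fell (16 and 1 adjusted over the list alone). Examples beside Smad7 and Skil were Pmepa1, which dampens SMAD signalling (2.53 ± 0.16), and Bambi. The list passed camera (adjusted p = 3.97e-08) but not with the correlation estimated from the data (adjusted p = 0.0846 with an estimated correlation). Of the unfolded protein response genes, 3 rose and 15 fell of 30 (4 and 18 adjusted over the list alone), including the protein disulfide isomerases Pdia6 (-1.26 ± 0.06, 833 ± 40.1 to 348 ± 24.0 CPM) and Pdia4 (-0.74 ± 0.05), the secreted chaperone Manf (-0.72 ± 0.06) and Sdf2l1 (-1.34 ± 0.11). This list passed camera with the preset and the estimated correlation (adjusted p 3.97e-08 and 7.58e-05). Members of the beta cell list changed in both directions, 6 up and 15 down of 35 (9 and 15 adjusted over the list alone), with decreases of the prohormone convertase Pcsk1 (-0.74 ± 0.07) and of the transcription factor Pdx1 (-0.48 ± 0.05) and an increase of the calcium channel Cacna1d (0.58 ± 0.06). The list did not pass camera (adjusted p = 0.0706). Of the other islet hormone genes, 2 rose and 6 fell of 9, with the same numbers adjusted over the list alone. Glucagon, Gcg (chromosome 2, 62474530 to 62483650, minus strand), fell from 52.8 ± 1.81 to 14.5 ± 0.0934 CPM (-1.87 ± 0.08) and the retinol carrier Rbp4 fell by 1.90 ± 0.09 (list adjusted p = 0.0535). Of the secretory granule genes 5 rose and 8 fell of 29 (5 and 11 adjusted over the list alone; list adjusted p = 0.518), with the serotonin synthesis enzymes Ddc (1.91 ± 0.09) and Tph1 (3.26 ± 0.17) up and carboxypeptidase E, Cpe (-0.97 ± 0.04), and secretogranin II, Scg2 (-1.14 ± 0.08), down.

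In the apoptosis list of control cells, 4 genes rose and 1 fell of 36 (2 and 0 adjusted over the list alone; list adjusted p = 0.941). Bmf (chromosome 2, 118528757 to 118549687, minus strand), a proapoptotic BCL2 family member of the BH3-only class, rose from 1.17 ± 0.198 to 10.9 ± 1.65 CPM (3.23 ± 0.15, adjusted p = 2.61e-14), and the death-associated kinase Dapk1 rose by 0.58 ± 0.07. Of the G1/S genes 0 rose and 7 fell of 30 (0 and 8 adjusted over the list alone; list adjusted p = 0.0535), among them E2f2 (-0.44 ± 0.07) and cyclin E1, Ccne1 (-0.31 ± 0.05). Of the progenitor genes 5 rose and 3 fell of 16, with the same numbers adjusted over the list alone (list adjusted p = 0.362), including Pax4, which directs endocrine precursors (2.89 ± 0.08), and Sox4 (1.38 ± 0.07). In the BMP target list 4 genes rose and 5 fell of 13 (5 and 5 adjusted over the list alone; list adjusted p = 0.518), with Id3, an inhibitor of helix-loop-helix factors, down by 1.74 ± 0.21 and the BMP antagonist Grem1 up by 1.71 ± 0.28.

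In total 3180 genes passed the edgeR test in control cells, 1671 higher and 1509 lower with activin B, and 4733 had an unadjusted p under 0.05. Of the calls, 328 rose and 248 fell by at least 2-fold. Control activin B replicate 2 had fewer reads on GC-rich genes (Spearman correlation of its gene-wise deviations with GC content -0.71), and across genes the log2 fold changes of this contrast correlated with GC content at -0.31. With only the control groups fitted 1734 genes were called, and with the GC correction and the replicate block within each line 5250.

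In cells labelled ALK7, activin B again raised Spon2 (5.18 ± 0.18 SE), Prr5l (5.06 ± 0.21), the metalloprotease Adamts7 (4.96 ± 0.32), Jam2 (4.92 ± 0.13) and Agt (4.61 ± 0.21). Large decreases were of the adaptor protein Lcp2 (-3.09 ± 0.17), Pdyn (-2.82 ± 0.13), Wfdc16 (-2.39 ± 0.19), the receptor kinase Ros1 (-2.28) and the glucose transporter Slc2a2 (-2.19 ± 0.20). Smad7 rose from 2.23 ± 0.197 to 16.9 ± 0.592 CPM (2.92 ± 0.12, adjusted p = 3.64e-15), Acvr1c fell by 0.93 ± 0.10 and Smad3 by 0.95 ± 0.09. Bmf rose by 3.71 ± 0.15 to 20.2 ± 0.202 CPM, Sox4 rose by 1.99 ± 0.07, and the hormone gene Ppy rose by 3.07 ± 0.40 from 0.153 CPM. Of the SMAD2/3 targets 17 rose and 0 fell of 30 (17 and 1 adjusted over the list alone), including Tgfb1 (3.80 ± 0.29) and Ldlrad4 (2.49 ± 0.12), a SMAD inhibitor. The list passed camera with the preset and the estimated correlation (adjusted p 1.11e-10 and 0.0427). The unfolded protein response list had 4 up and 18 down (4 and 19 adjusted over the list alone), with the chaperone Hspa5 down by -0.94 ± 0.06 and Pdia6 by -1.40 ± 0.06, and passed with both correlations (adjusted p 5.19e-09 and 3.46e-05). In the G1/S list 0 genes rose and 13 fell of 30, also adjusted over the list alone, such as the replication licensing factor Cdc6 (-0.44 ± 0.06) and Ccne1 (-0.40 ± 0.05), and this list passed too (adjusted p 0.00276 and 0.0139).

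A further 4 lists passed camera in ALK7 cells only with the preset correlation. BMP targets had 6 up and 1 down of 13 (7 and 2 adjusted over the list alone), with Id2 up by 0.57 ± 0.06 (list adjusted p = 0.0196, and adjusted p = 0.102 with an estimated correlation). Id3, also of this list, went the other way, from 29.5 ± 6.60 to 14.8 ± 1.58 CPM. The list did not pass with the replicate block within each line (adjusted p = 0.0821), with only these groups fitted (0.112) or with the GC correction (0.0534). Extracellular matrix genes had 9 up and 2 down of 23, also adjusted over the list alone, with the laminin chains Lamb1 (3.12 ± 0.12) and Lama1 (1.24 ± 0.12) up (list adjusted p = 0.0209, and adjusted p = 0.304 with an estimated correlation). The list did not pass without ALK7 activin B replicate 1 (adjusted p = 0.0508), without the low-count filter (0.0999), in limma-trend (0.471), or with GC and length corrected (0.0757). Cholesterol synthesis genes had 0 up and 6 down of 23, also adjusted over the list alone, among them Tm7sf2 (-0.82 ± 0.09; list adjusted p = 0.0209, and adjusted p = 0.304 with an estimated correlation). Without ALK7 activin B replicate 1 the list p was 0.0600. Glycolysis genes had 1 up and 8 down of 21, also adjusted over the list alone, with hexokinase Hk1 down by -0.82 ± 0.10 (list adjusted p = 0.0310, and adjusted p = 0.357 with an estimated correlation). This call ended without ALK7 DOX replicate 1 (adjusted p = 0.0913) or ALK7 activin B replicate 1 (0.0508), with only these groups fitted (0.0658), in DESeq2 (0.0768) and in limma-trend (0.0694). In total 3953 genes passed, 2032 higher and 1921 lower, and 6082 with the GC correction and the block. Across genes the log2 fold changes correlated with GC content at 0.33.

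In cells labelled ALK7-DN, a form built to block ALK7 signalling, the same feedback genes responded. Smad7 rose from 2.39 ± 0.204 to 10.9 ± 1.18 CPM (2.18 ± 0.12 SE, adjusted p = 9.92e-13), Skil by 1.67 ± 0.08 and Bambi by 1.59 ± 0.06, and Smad3 fell by 0.96 ± 0.09. Large increases were of Prr5l (5.33 ± 0.22), Jam2 (4.61 ± 0.14), the channel-like protein Tmc7 (3.62 ± 0.14) and Tph1 (3.61 ± 0.18). Large decreases were of Lcp2 (-2.20 ± 0.16), Wfdc16 (-2.14 ± 0.18) and Pdyn (-2.14 ± 0.13). Bmf rose by 2.46 ± 0.14, Pax4 by 2.63 ± 0.08, and Gcg fell by 1.72 ± 0.08. Acvr1c fell by 0.59 ± 0.10 (adjusted p = 0.000157), but not past the test once a batch term from the hairpin lines was fitted (-0.23, adjusted p = 0.371). That term assumes equal responses of the hairpin lines and cannot tell batch from a difference between them. Of the SMAD2/3 targets 14 rose and 1 fell of 30 (14 and 2 adjusted over the list alone; list adjusted p = 1.91e-07, and adjusted p = 0.144 with an estimated correlation). The unfolded protein response list had 2 up and 12 down (2 and 17 adjusted over the list alone), with Pdia6 at -0.97 ± 0.06 and Hspa5 at -0.68 ± 0.06, and passed with both correlations (adjusted p 1.91e-07 and 6.52e-05). In total 2515 genes passed, 1325 higher and 1190 lower, 4096 with the batch term, and with the GC correction and the block 4527. In this line the activin B arm was all of batch 2, so treatment and batch coincided.

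In sh2 cells, activin B raised Jam2 (4.33 ± 0.14 SE), Spon2 (4.19 ± 0.18), the thyroid hormone deiodinase Dio2 (3.84 ± 0.23) and Tmc7 (3.80 ± 0.14). Decreases included Pdyn (-3.29 ± 0.14), Gcg (-2.64 ± 0.08, from 52.7 ± 0.813 to 8.48 ± 1.05 CPM), C1qa (-2.44 ± 0.16), Gbx2 (-2.28 ± 0.20), Lcp2 (-2.27 ± 0.16) and secretin, Sct (-2.26 ± 0.28). Smad7 rose by 2.01 ± 0.12, Skil by 1.81 ± 0.08 and Bmf by 2.53 ± 0.15, and Smad3 fell by 0.82 ± 0.09 and Acvr1c by 0.68 ± 0.11. Of the SMAD2/3 targets 15 rose and 1 fell of 30 (18 and 2 adjusted over the list alone; list adjusted p = 6.01e-08, and adjusted p = 0.121 with an estimated correlation). The unfolded protein response list had 1 up and 15 down (2 and 17 adjusted over the list alone) and passed with both correlations (adjusted p 6.01e-08 and 7.62e-05), with Pdia6 at -1.06 ± 0.06 and Sdf2l1 at -1.11 ± 0.11. Glycolysis genes had 0 up and 8 down of 21 (0 and 9 adjusted over the list alone), among them Hk1 (-0.84 ± 0.10) (list adjusted p = 0.000213, and adjusted p = 0.127 with an estimated correlation). G1/S genes had 0 up and 5 down of 30, also adjusted over the list alone, with Ccne1 at -0.38 ± 0.05 (list adjusted p = 0.0281, and adjusted p = 0.0870 with an estimated correlation), a call that ended without sh2 DOX replicate 1 (adjusted p = 0.0569) or 3 (0.0599). In total 3070 genes passed, 1677 higher and 1393 lower, and 5449 with the GC correction and the block. The DOX arm was all of batch 2.

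In sh1/2 cells, which had the lowest Acvr1c counts, activin B raised Prr5l (5.19 ± 0.24 SE), Ltbp2 (3.54 ± 0.21), Spon2 (3.43 ± 0.18), Fam210b (3.25 ± 0.05), Tgfb1 (3.21 ± 0.27) and Jam2 (3.15 ± 0.13). The pseudogene Tpt1-ps6, which may share reads with its parent gene, had a fitted increase of 5.45 ± 1.06 (17.4 ± 27.7 CPM). Decreases included Gcg (-2.43 ± 0.08, from 164 ± 6.57 to 30.5 ± 0.984 CPM), Wfdc16 (-2.34 ± 0.19), the synaptic protein C1ql3 (-2.21 ± 0.13), the urea cycle enzyme Otc (-2.17 ± 0.30) and Rasgef1c (-2.10 ± 0.25). Smad7 rose by 1.71 ± 0.12, Skil by 1.13 ± 0.07 and Bmf by 1.70 ± 0.15, while Acvr1c fell by 1.05 ± 0.11, Smad3 by 0.65 ± 0.09 and the BMP-linked Smad9 by 0.78 ± 0.07. Of the SMAD2/3 targets 16 rose and 1 fell of 30 (17 and 1 adjusted over the list alone; list adjusted p = 5.99e-07, and adjusted p = 0.242 with an estimated correlation). The unfolded protein response list had 4 up and 18 down, also adjusted over the list alone, and passed with both correlations (adjusted p 0.00145 and 0.0115), with Hspa5 and Pdia6 both at -0.64 ± 0.06. In total 5723 genes passed, 2731 higher and 2992 lower, and 1555 with only the sh1/2 groups fitted. The log2 fold changes correlated with GC content at 0.74 across genes, as sh1/2 DOX replicates 1 and 3 had fewer reads on GC-rich genes (Spearman -0.63 and -0.67, against 0.24 in replicate 2). Without sh1/2 DOX replicate 1 or 3 the test called 3055 or 2974 genes, and without both and control activin B replicate 2 it called 1476.

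**Figure D3:**
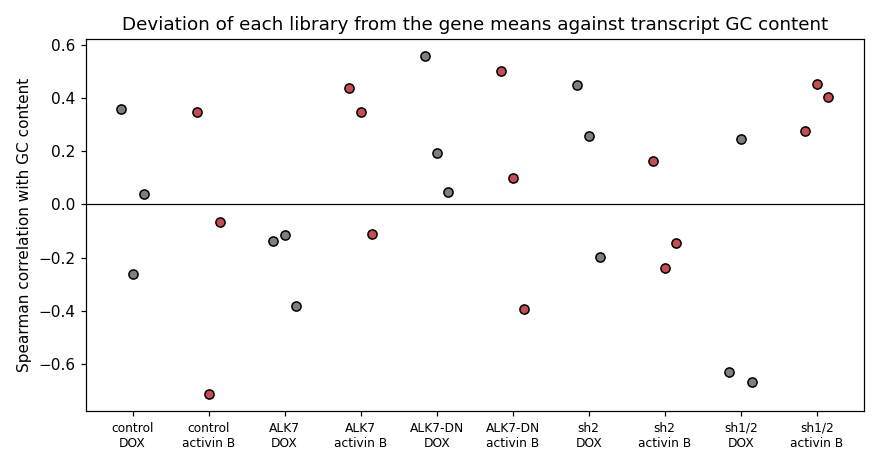
Spearman correlation between transcript GC content and each library's deviation from the gene means (y axis, no unit) by group (x axis), with 1 point per library. Control activin B replicate 2 (-0.71) and sh1/2 DOX replicates 1 and 3 (-0.63 and -0.67) lie below -0.5.

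Across lines, the activin B response was asked to recur. These contrasts share no library. In all 5 lines 677 genes were called higher and 553 lower, of 8418 called in at least 1 line, and 105 genes were called in opposite directions in some pair of lines. Control and ALK7 cells shared 1226 genes called higher, against 217 from independent lists, and 1077 called lower, against 185. Control and ALK7-DN cells shared 1150 higher and 1003 lower (independent lists 142 and 115). Control and sh2 cells shared 1226 and 1032 (179 and 135). Control and sh1/2 cells shared 862 and 785 (292 and 289). By mean log2 fold change over the lines, shared genes with a high value were Prr5l (5.44), Tmem91 (5.28) and the myosin-binding protein Mybpc1 (4.56). Next came Nags, which starts the urea cycle (4.44), the peptidylarginine deiminase Padi1 (4.36), Spon2 (4.31), Jam2 (4.30) and the cation channel Trpc7 (4.01). Unlike the genes named per line, this ranking had no minimum CPM, and some means hide a wide range. Mybpc1 ran from 2.31 in sh1/2 to 7.95 in ALK7 cells. Padi1 ran from 2.40 in ALK7-DN to 8.01 in ALK7 cells. With only the groups of each contrast fitted, 698 genes were shared in place of 1230, and with the GC correction and the block 2074.

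The interaction terms asked whether a line responded to activin B differently from the control. Between ALK7 and control cells, Marcksl1, an actin-regulating substrate of protein kinase C, had the higher log2 fold change in ALK7 cells (difference 1.00 ± 0.14 SE, adjusted p = 0.00224, edgeR), as did Sox4 (0.60 ± 0.09, adjusted p = 0.00995) and the dynamin Dnm3 (0.54 ± 0.09, adjusted p = 0.0313), and the calcium-binding protein Scgn had the lower one, a larger fall (-0.42 ± 0.07, adjusted p = 0.0294). Smad7 differed by 0.62 ± 0.17 (adjusted p = 0.263). With only the 4 groups fitted none of these genes passed (adjusted p 0.0606, 0.172, 0.249 and 0.249 for differences of 0.99, 0.60, 0.53 and -0.43). Sox4 did not pass without control DOX replicate 1 (adjusted p = 0.0839), ALK7 DOX replicate 2 (0.0654) or ALK7 activin B replicate 1 (0.0543). Dnm3 held only without control DOX 2 or control activin B 1. Scgn held only without those or control activin B 3. Without control DOX 1 their adjusted p were 0.175 and 0.161. These 4 genes were all that passed, with 1595 at an unadjusted p under 0.05, and 2 passed without the low-count filter, 8 in limma-trend, 33 in DESeq2 and 32 with the GC correction. The replicate block raised the count to 27, and the block within each line to 205 and, with the GC correction, to 469. The count fell to 1 without control DOX 1, ALK7 DOX 2 or ALK7 activin B 1 and to 2 without control DOX 3, control activin B 2, ALK7 DOX 1 or 3, or ALK7 activin B 2 or 3, and it rose to 21 without control activin B 1. Across genes the difference correlated with GC content at 0.69.

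As lists, the SMAD2/3 targets lay higher in the difference of ALK7 from control cells (adjusted p = 0.00215, and adjusted p = 0.413 with an estimated correlation), with 0 members past the test over all genes and 2 higher adjusted over the list alone. The BMP targets (adjusted p = 0.00127, and adjusted p = 0.0802 with an estimated correlation; 2 higher adjusted over the list alone), the extracellular matrix genes (0.00836, and adjusted p = 0.283 with an estimated correlation) and the calcium and cAMP genes (0.00127, and adjusted p = 0.354 with an estimated correlation) also lay higher. A higher difference can be a smaller fall. Id3 of the BMP list went from 67.3 ± 4.47 to 20.1 ± 3.56 CPM in control cells. In ALK7 cells it went from 29.5 ± 6.60 to 14.8 ± 1.58 CPM. The cholesterol genes lay lower (adjusted p = 0.00127, and adjusted p = 0.222 with an estimated correlation; 5 lower adjusted over the list alone). So did the unfolded protein response genes (0.0244, and adjusted p = 0.0917 with an estimated correlation), a call that ended without control DOX 2 (0.0701), control activin B 1 (0.0733) or 3 (0.0868), or ALK7 activin B 2 (0.0713). The matrix call also ended without the low-count filter (0.242), in limma-trend (0.455) and with the GC correction and the block (0.0797).

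Between ALK7-DN and control cells 0 genes passed in edgeR, and 342 of the 15627 tested had an unadjusted p under 0.05. This is below the share of 0.05 that unchanged genes would give, so the 342 do not by themselves point to differences. There were 3 calls in DESeq2, 5 with the batch term, and 1 each with only the 4 groups fitted and with the replicate block within each line. Smad7 differed by -0.11 ± 0.17 and Acvr1c by 0.12 ± 0.15 (adjusted p = 1.00 for both). As lists, the other islet hormone genes (adjusted p = 0.00852, and adjusted p = 0.0255 with an estimated correlation; 1 higher adjusted over the list alone) and the unfolded protein response genes (0.00765, and adjusted p = 0.0221 with an estimated correlation) lay higher in the difference, and both calls ended without control activin B replicate 1 (0.0508 each) and without ALK7-DN DOX 1 (0.0966) or ALK7-DN activin B 3 (0.0672) respectively. Secretory granule (0.0172) and cholesterol genes (0.0172) lay higher and epithelial-mesenchymal transition genes (0.0172) lower, and none of these calls held without control activin B 1 (0.0508, 0.0508 and 0.0922). They had adjusted p = 0.164, adjusted p = 0.427 and adjusted p = 0.50005 with an estimated correlation. The ALK7-DN activin B arm was all of batch 2, so batch and response cannot be told apart here.

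Between sh2 and control cells, Gcg fell further in sh2 cells (difference -0.77 ± 0.11 SE, adjusted p = 0.00574, edgeR) and Id2 (chromosome 12, 25093799 to 25097140, minus strand) also had the lower log2 fold change (-0.47 ± 0.08, adjusted p = 0.0465). Only these 2 genes passed in edgeR, and 13 with the GC correction and the block. An unadjusted p under 0.05 in edgeR was held by 527 of the 15627 genes, also below a share of 0.05. Id2 was lost with the replicate block within each line (adjusted p = 0.102), the GC correction (0.103), GC and length corrected (0.192), no low-count filter (0.119) or without the 3 GC-poor libraries (0.118), although the difference stayed between -0.47 and -0.43. Leaving out 1 library gave 1 called gene in 10 of 12 cases, all but control activin B 1 and sh2 activin B 1. With only the 4 groups fitted, neither passed (adjusted p = 0.140 for both, Gcg at -0.77 and Id2 at -0.47). DESeq2 called 5 genes, and 1 passed without the low-count filter. The BMP targets as a list lay lower in the difference of sh2 from control cells with both correlations (adjusted p 5.84e-06 and 0.00472; 1 lower, and 2 adjusted over the list alone). Glycolysis genes (6.36e-06; 3 lower adjusted over the list alone) and calcium and cAMP genes (0.000138) had adjusted p = 0.0882 and adjusted p = 0.346 with an estimated correlation. The sh2 DOX arm was all of batch 2, so batch and response cannot be told apart here. Id2 stood at 89.5 ± 1.71 CPM in sh2 against 65.9 ± 0.508 in control cells under DOX alone, but at 74.0 ± 3.58 against 75.3 ± 0.882 with activin B, where both were in batch 1. Gcg went the other way, at 52.7 ± 0.813 against 52.8 ± 1.81 CPM under DOX alone and 8.48 ± 1.05 against 14.5 ± 0.0934 with activin B (-0.77 ± 0.08, adjusted p = 4.52e-07). The BMP list was not called between these lines with activin B (adjusted p = 0.768). In sh1/2 cells, all of batch 1, Id2 stood at 92.2 ± 1.97 CPM under DOX alone and at 55.9 ± 5.33 with activin B. The BMP list was higher in sh1/2 than in control cells under DOX alone (camera adjusted p = 0.0140, and 0.103 with an estimated correlation).

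Between sh1/2 and control cells, Agt (difference -1.93 ± 0.27 SE, adjusted p = 0.000225, edgeR), the cadherin Cdh17 (-1.69 ± 0.28, adjusted p = 0.000986), Bmf (-1.53 ± 0.21, adjusted p = 0.000194), the metalloprotease Adamts6 (-1.49 ± 0.21) and the vitamin D-binding protein Gc (-1.44 ± 0.09, adjusted p = 3.98e-10) had lower log2 fold changes in sh1/2 cells. These calls held without each single library and with the GC correction. They also held without the 3 GC-poor libraries, a fit with 1 library left in the sh1/2 DOX arm, so the spread came from the other groups. Pax4 (-0.81 ± 0.11) and Id2 (-0.92 ± 0.08) also had lower log2 fold changes, and Pdia6 (0.62 ± 0.09) and Sdf2l1 (0.99 ± 0.15), which fell in control cells, had higher ones. Smad7 differed by -0.59 ± 0.17 (adjusted p = 0.0313), a call that ended without the 3 GC-poor libraries (-0.41, adjusted p = 0.730), without control DOX 2 (0.0538), sh1/2 DOX 1 (0.111) or 3 (0.103), or sh1/2 activin B 2 (0.0673) or 3 (0.0592). With activin B, Smad7 stood at 13.7 ± 0.492 CPM in sh1/2 and 13.7 ± 1.63 CPM in control cells. Under DOX alone it stood at 4.21 ± 0.636 against 2.81 ± 0.456 CPM. The mean Smad7 levels of these lines thus differed under DOX alone and not with activin B. Acvr1c differed by -0.34 ± 0.15 (adjusted p = 0.1004). Positive differences included 3 genes with near-identical copies, Tpt1-ps6 (5.95 ± 1.62), Pgk1-rs7 (5.05 ± 1.73) and Rpl31-ps8 (2.169 ± 0.72), the beta cell transcription factor Mafa (chromosome 15, 75745490 to 75748228, minus strand; 2.47 ± 0.73, adjusted p = 0.0353) and the convertase inhibitor Pcsk1n (2.168 ± 0.74). Mafa did not pass without control activin B 2 (2.14, adjusted p = 0.125), sh1/2 DOX 1 (2.32, 0.110) or sh1/2 DOX 3 (2.06, 0.110), and Pcsk1n did not pass with the GC correction (1.79, 0.0743) or without the 3 GC-poor libraries (0.83). Pcsk1n also did not pass without control DOX 1 (adjusted p = 0.120) or 3 (0.0788), control activin B 2 (0.154) or 3 (0.0561), sh1/2 DOX 1 (0.137) or 3 (0.147), or sh1/2 activin B 2 (0.102) or 3 (0.0779). The 3 libraries that ended the Mafa call are the GC-poor ones, and the Mafa transcript has 65.0% GC content. Mafa went from 9.33 ± 7.65 to 15.8 ± 3.24 CPM in sh1/2 cells, with counts of 51 to 569 under DOX alone. In control cells it went from 18.8 ± 6.14 to 5.54 ± 2.69 CPM. Tpt1-ps6 stood at 2.30 without sh1/2 activin B 1, Pgk1-rs7 at -0.11 without control DOX 1 and Rpl31-ps8 at 0.35 without sh1/2 activin B 2. The BMP list lay lower (0 up and 5 down of 13, also adjusted over the list alone; adjusted p = 0.0150, and adjusted p = 0.104 with an estimated correlation) and did not pass with the block within each line (0.0538) or without sh1/2 DOX 2 (0.215).

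In all, 2768 genes passed the sh1/2 interaction test, 1327 higher and 1441 lower, with 6132 at an unadjusted p under 0.05. Across genes the difference correlated with GC content at 0.80, 961 genes passed after the GC correction (353 higher), 64 without the 3 GC-poor libraries (23 higher), 45 with only the 4 groups fitted (14 higher), 989 without the low-count filter, 4704 with the replicate block and 5956 with the block within each line. Single libraries moved the count to 411 (without control DOX 1), 687 (control DOX 3), 5111 (control activin B 1), 324 (control activin B 2), 289, 6983 and 303 (sh1/2 DOX 1, 2 and 3), and 507 and 528 (sh1/2 activin B 2 and 3).

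**Figure D4:**
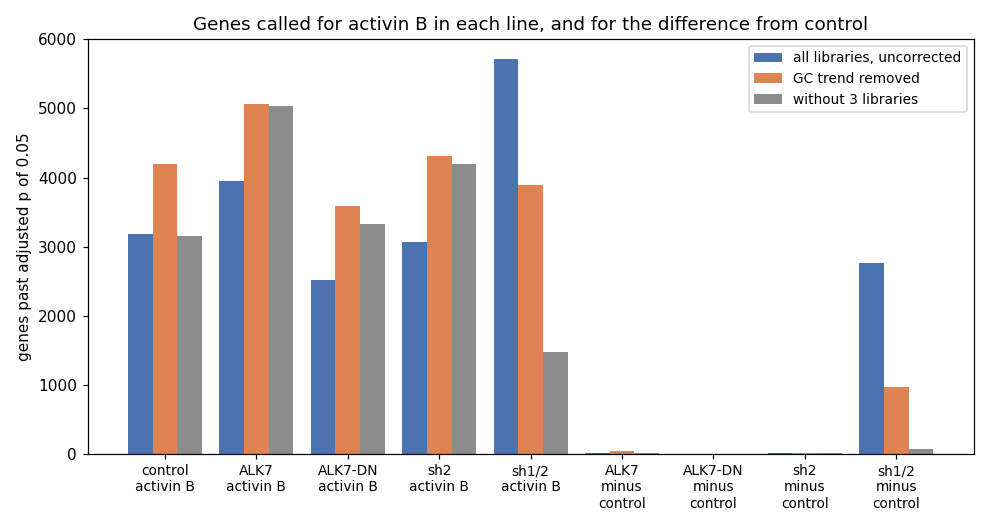
Number of genes past the adjusted p threshold (y axis, from 0) for the 5 activin B contrasts and the 4 interaction terms (x axis), uncorrected with all libraries, after the GC correction, and without the 3 GC-poor libraries. The sh1/2 interaction count drops from 2768 to 961 and to 64.

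The remaining comparisons asked how the lines differed from the control without activin B. In ALK7 cells the axon guidance gene Slit2 (2.93 ± 0.22 SE, from 0.775 to 5.91 CPM), the imprinted gene Peg10 (2.21 ± 0.13), the complement inhibitor Serping1 (1.17 ± 0.12) and fructose bisphosphatase Fbp1 (0.87 ± 0.10) were higher. The ion pump subunit Fxyd2 (-1.47 ± 0.19), Id3 (chromosome 4, 136143497 to 136145755, plus strand; -1.19 ± 0.20), Id2 (-0.71 ± 0.06), Smad9 (-0.41 ± 0.07) and the sorting receptor Sorcs1 (-0.90 ± 0.07) were lower. The BMP list had 1 up and 4 down of 13 (2 and 5 adjusted over the list alone; adjusted p = 0.00690, and adjusted p = 0.0759 with an estimated correlation). The cholesterol list had 0 up and 3 down of 23 (0 and 13 adjusted over the list alone) and passed with both correlations (adjusted p 2.62e-11 and 0.00744). Among its members, Lss (-0.22) and Sqle (-0.23) passed but lost their call without any 1 of the 6 libraries (adjusted p without control DOX 1 0.0966 and 0.0849). In total 310 genes passed, 161 higher and 149 lower. Without control DOX 1 or 3 the count was 161 or 151, and without ALK7 DOX 1, 2 or 3 it was 157, 156 or 162. It was 159 with only these groups fitted, 186 without the low-count filter, 529 with the replicate block and 786 with the GC correction.

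In ALK7-DN cells, Peg10 (0.97 ± 0.13), the neuronal vesicle protein Nsg2 (0.81 ± 0.08) and the galectin Lgals2 (0.71 ± 0.09) were higher. The glutamate transporter Slc1a2 (-1.03 ± 0.12), protein kinase C beta, Prkcb (-0.81 ± 0.08), and Gc (-0.52 ± 0.06) were lower. The incretin Gip (0.68 ± 0.09) passed in the fit of all groups but not with only these libraries (adjusted p = 0.0503). No list passed camera, and the SMAD2/3 and BMP lists had 0 members called in either direction, with 0 adjusted over the list alone. In total 151 genes passed, 59 higher and 92 lower. The count was 88, 83 or 75 without control DOX 1, 2 or 3 and 80, 67 or 73 without ALK7-DN DOX 1, 2 or 3. It was 25 (6 higher) with only these groups fitted, 91 without the low-count filter and 273 with the GC correction.

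In sh1/2 cells increases included the calcium release channel Ryr1 (5.31 ± 0.39), Gip (4.84 ± 0.10, 843 ± 14.5 against 29.3 ± 2.15 CPM), Otc (4.41 ± 0.37), Neurl3 (4.21 ± 0.26) and Spink4 (3.53 ± 0.14). Decreases included Slc1a2 (-2.96 ± 0.15), the protease Pappa2 (-2.74 ± 0.10), Lrrn2 (-2.47 ± 0.22), the splicing factor Celf2 (-2.11 ± 0.11) and the hedgehog-binding protein Hhip (-1.99 ± 0.13). Cholesterol synthesis genes fell together, 0 up and 22 down of 23, also adjusted over the list alone, such as Tm7sf2 (-1.08 ± 0.09) and Dhcr7 (-0.90 ± 0.06), with both correlations (adjusted p 3.45e-17 and 0.000332). Fatty acid genes had 3 up and 14 down of 30, also adjusted over the list alone, including the desaturases Scd2 (-1.16 ± 0.05) and Scd1 (-1.09 ± 0.07) (adjusted p 0.000268 and 0.0466). Other islet hormone genes had 7 up and 0 down of 9 (8 and 0 adjusted over the list alone), with Gcg at 164 ± 6.57 against 52.8 ± 1.81 CPM (1.63 ± 0.07) and Rbp4 at 1.92 ± 0.09 (adjusted p 1.49e-08 and 0.000130). Calcium and cAMP early genes had 15 up and 1 down of 26, also adjusted over the list alone, such as Nr4a1 (1.71 ± 0.18) and Egr1 (1.60 ± 0.16) (list adjusted p = 9.24e-06, and adjusted p = 0.165 with an estimated correlation). Glycolysis genes had 2 up and 11 down of 21 (3 and 13 adjusted over the list alone), such as Aldoc (-0.89 ± 0.09) (list adjusted p = 0.00940, and adjusted p = 0.276 with an estimated correlation).

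Another 3 lists passed in sh1/2 cells with the preset correlation. Interferon genes had 4 up and 12 down of 30, also adjusted over the list alone, such as Usp18 (-0.50 ± 0.05; list adjusted p = 0.0236, and adjusted p = 0.288 with an estimated correlation), and did not pass without control DOX 2 (0.0504) or sh1/2 DOX 2 (0.1003). BMP genes had 6 up and 2 down of 13 (7 and 2 adjusted over the list alone), with Id1 (chromosome 2, 152736251 to 152737410, plus strand) at 1.79 ± 0.22 (list adjusted p = 0.0140, and adjusted p = 0.103 with an estimated correlation), and did not pass without sh1/2 DOX 2 (0.0617). Epithelial-mesenchymal transition genes had 6 up and 0 down of 17 (7 and 0 adjusted over the list alone), with the transcription factor Snai2 at 0.96 ± 0.12 (list adjusted p = 0.0381, and adjusted p = 0.355 with an estimated correlation), and did not pass without control DOX 2 (0.0504) or sh1/2 DOX 1 (0.101) or 2 (0.0617). In total 5934 genes passed, 3033 higher and 2901 lower, 2430 with only these groups fitted and 3351 without the 3 GC-poor libraries, of which this contrast holds a pair. Across genes the log2 fold changes correlated with GC content at -0.48.

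For sh2 the arm with activin B compared lines within one batch. There Gip (2.11 ± 0.10), Spink4 (1.97 ± 0.14), the semaphorin Sema6a (1.48 ± 0.12) and the glutamate transporter Slc17a6 (1.17 ± 0.20) were higher. Lower were Pappa2 (-3.32 ± 0.11, 13.6 ± 1.03 against 136 ± 6.63 CPM), Slc1a2 (-2.18 ± 0.12), Mlph (-1.99 ± 0.20), the adhesion molecule Nrcam (-1.99 ± 0.17) and the calcium channel Cacna1e (-1.96 ± 0.13). Interferon genes had 0 up and 6 down of 30, also adjusted over the list alone, such as Usp18 (-0.47 ± 0.05; list adjusted p = 0.00586, and adjusted p = 0.214 with an estimated correlation). Cholesterol genes had 0 up and 5 down of 23, also adjusted over the list alone (list adjusted p = 0.00574, and adjusted p = 0.214 with an estimated correlation). Fatty acid genes had 0 up and 8 down of 30 (1 and 10 adjusted over the list alone), such as Cpt1a (-0.53 ± 0.05; list adjusted p = 0.00586, and adjusted p = 0.214 with an estimated correlation), and did not pass without control activin B 1 (0.0818). G1/S genes had 3 up and 0 down of 30, also adjusted over the list alone, such as Cdc45 (0.20 ± 0.04; list adjusted p = 0.0117, and adjusted p = 0.0900 with an estimated correlation). In total 1443 genes passed, 478 higher and 965 lower, 440 when only these libraries were fitted and 2381 with the GC correction.

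Under DOX alone, where sh2 was in batch 2 and the control in batch 1, Rgs13 (1.95 ± 0.24), Gip (1.87 ± 0.09, 107 ± 9.52 against 29.3 ± 2.15 CPM) and Spink4 (1.84 ± 0.14) were higher and Pappa2 (-3.22 ± 0.11), Slc1a2 (-2.52 ± 0.14), Cacna1e (-2.44 ± 0.15) and Nrcam (-1.93 ± 0.17) lower in sh2. With the preset correlation 7 lists passed and none of them with the estimated one. Receptors, ligands and SMADs had 0 up and 4 down of 22, also adjusted over the list alone (list adjusted p = 0.0325, and adjusted p = 0.316 with an estimated correlation), and extracellular matrix genes 0 up and 4 down of 23 (0 and 5 adjusted over the list alone), such as Lama1 (-1.30 ± 0.13; 0.0325, and adjusted p = 0.316 with an estimated correlation). BMP targets had 3 up and 1 down of 13 (6 and 2 adjusted over the list alone) and progenitor genes 6 and 0 of 16, also adjusted over the list alone, such as Pax4 (0.55 ± 0.08), each at 0.0325, and adjusted p = 0.196 with an estimated correlation. Both calls ended without control DOX 2 (0.0974 and 0.115) and that of the BMP list without sh2 DOX 1 (0.0517). Both also ended with the GC correction (0.0753 and 0.102) and with GC and length corrected (0.121 and 0.147). The receptor and matrix calls ended with GC and length corrected (0.112 each), and the matrix call with only these groups fitted (0.109) and in limma-trend (0.172). Fatty acid genes had 1 up and 7 down of 30 (1 and 9 adjusted over the list alone; 0.00728, and adjusted p = 0.196 with an estimated correlation). Glycolysis genes had 6 up and 0 down of 21 (7 and 1 adjusted over the list alone; 0.00728, and adjusted p = 0.238 with an estimated correlation), and G1/S genes 3 up and 0 down of 30, also adjusted over the list alone (0.00728, and adjusted p = 0.0530 with an estimated correlation). In total 1561 genes passed, 524 higher and 1037 lower, 863 with only these groups fitted, 2789 with the batch term and 2591 with the GC correction; line and batch coincide in this comparison.

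The apoptosis, beta cell identity, p53 target, G2/M, cyclin and kinase, exocrine and duct, stromal, endothelial and immune, and SV40-related lists passed camera in none of the 14 contrasts. Their lowest adjusted p were 0.286, 0.0706, 0.338, 0.0548, 0.345, 0.289, 0.299 and 0.289. The secretory granule list passed in 1 contrast only, as given above. Over the 322 list tests, 53 passed with the preset correlation and 14 of these with an estimated one. In 104 list tests the median, the mean and the test differed in sign, and 0 of these passed.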

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

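The tests of GC content, of response size, of sh2 against batch and plasmid, and of exchanged line labels were chosen only after the results were seen.

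Responses to activin B that differed between a line and the control, by the interaction test in edgeR, were flagged. Between ALK7 and control cells 4 genes differed: Marcksl1 (1.00), Sox4 (0.60), Dnm3 (0.54) and Scgn (-0.42). The lists that passed with the preset correlation were SMAD2/3 targets (adjusted p = 0.00215), BMP targets (0.00127), extracellular matrix (0.00836), unfolded protein response (0.0244), cholesterol synthesis (0.00127) and calcium and cAMP genes (0.00127). None of the 6 held with an estimated one, in that order adjusted p = 0.413, 0.0802, 0.283, 0.0917, 0.222 and 0.354 with an estimated correlation. The count was 21 without control activin B 1 and 1 without control DOX 1, ALK7 DOX 2 or ALK7 activin B 1. It was 2 without control DOX 3, control activin B 2, ALK7 DOX 1 or 3, or ALK7 activin B 2 or 3. Of the 40 relabellings of treatment within lines, 9 called as many genes as the 4 found (highest other 4981), and of the 40 exchanges of line labels within each arm, 9 did (highest other 1157). The median of the other relabellings and of the other exchanges was 0 calls in all 4 interactions, and some gave more calls than the real labels. A relabelling mixes the lines' responses, or the differences between lines, into the test or into its spread. For this and the following interactions these counts therefore decide nothing about chance.

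Between ALK7-DN and control cells only lists passed, with the preset correlation: secretory granule (adjusted p = 0.0172), other islet hormone genes (0.00852), epithelial-mesenchymal transition (0.0172), unfolded protein response (0.00765) and cholesterol synthesis (0.0172). The secretory granule, epithelial-mesenchymal transition and cholesterol calls ended, with adjusted p = 0.164, adjusted p = 0.50005 and adjusted p = 0.427 with an estimated correlation. None of the 5 held without control activin B 1 (0.0508 for 4 of them and 0.0922 for epithelial-mesenchymal transition). The gene count was 0 in edgeR and 3 in DESeq2. In edgeR 342 of the 15627 genes had an unadjusted p under 0.05, below the share of 0.05 that unchanged genes would give. A count of 0 is reached by all 40 relabellings (highest other 2134) and all 40 line exchanges (highest other 35) by definition, which decides nothing. The ALK7-DN activin B arm was all of batch 2, so batch and a difference in response cannot be told apart here.

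Between sh2 and control cells 2 genes differed, Gcg (-0.77) and Id2 (-0.47), with the BMP (adjusted p = 5.84e-06), glycolysis (6.36e-06) and calcium and cAMP lists (0.000138). The latter 2 lists ended, with adjusted p = 0.0882 and adjusted p = 0.346 with an estimated correlation. The sh2 DOX arm was all of batch 2, so batch and a difference in response cannot be told apart in this interaction. As many genes were called in 7 of 40 relabellings (highest other 5141) and in 7 of 40 line exchanges (highest other 3138). Id2 held only without sh2 activin B 1 (adjusted p = 0.0350), and without any of the other 11 libraries it did not pass (0.0760 without control activin B 2 to 0.271 without sh2 activin B 2).

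Between sh1/2 and control cells 2768 genes differed, among them Tpt1-ps6 (5.95), Pgk1-rs7 (5.05), Mafa (2.47), Rpl31-ps8 (2.169) and Pcsk1n (2.168) upward and Agt (-1.93), Cdh17 (-1.69), Bmf (-1.53), Adamts6 (-1.49) and Gc (-1.44) downward, with the BMP list (adjusted p = 0.0150, and adjusted p = 0.104 with an estimated correlation). Tpt1-ps6 stood at 2.30 without sh1/2 activin B 1, Pgk1-rs7 at -0.11 without control DOX 1 and Rpl31-ps8 at 0.35 without sh1/2 activin B 2. Mafa did not pass when control activin B 2, sh1/2 DOX 1 or sh1/2 DOX 3, the GC-poor libraries, was left out singly. The BMP list did not pass without sh1/2 DOX 2 (0.215). As many genes were called in 4 of 40 relabellings (highest other 3825) and in 5 of 40 line exchanges (highest other 3893). The count itself moved to 411 without control DOX 1, 687 without control DOX 3, 5111 without control activin B 1, 324 without control activin B 2, 289, 6983 and 303 without sh1/2 DOX 1, 2 and 3, and 507 and 528 without sh1/2 activin B 2 and 3.

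For the sh1/2 interaction, GC content bias was weighed against a difference in the lines' response. After the GC correction 598 of the 2768 genes were still called in the same direction, which argues against the fitted GC trend as the whole cause. The correction removes only a smooth trend, so other effects of the GC-poor libraries would remain after it and stay open. Over all 2768 the median absolute difference fell from 0.48 to 0.20 (median SE 0.14), a ratio of 0.421, so GC bias may account for part of it. The ratio of 0.337 in the calls that ended was fixed by choosing those genes and decides nothing. In counts simulated with the real GC trends and no changed gene, the uncorrected test called 0 genes in this interaction, though a simulation excludes nothing by itself. How far GC bias made the count stays open. Without the 3 GC-poor libraries 56 of the 2768 were still called, with 1 library left in the sh1/2 DOX arm. A difference in the response of sh1/2 cells stays open for the genes kept, beside a difference between the plasmids and clonal differences, which were not tested.

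For the differences of sh2 from the control, batch, plasmid and the knock-down were weighed. With activin B, where both lines were in batch 1, the calls shared in direction with sh1/2 against control under DOX alone were 311 higher and 569 lower, 3.24 times the number from independent lists, with 81 opposite. These contrasts share no library and lie within batch 1, so the batch label could not enter the shared calls. Both use the same control line, which the number from independent lists does not allow for. The sh2 calls under DOX alone, where line and batch coincide, are not decided by this. The plasmid of both hairpin lines had 0 lines without a hairpin, so plasmid and knock-down cannot be told apart.

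For the activin B calls of ALK7-DN and sh2 cells, whose arms were split between batches, a batch difference as the whole cause was weighed. It would enter these contrasts with opposite signs, yet their log2 fold changes correlated at 0.495 across genes, which argues against it. A smaller share of batch in single genes stays open. Acvr1c in ALK7-DN cells stood at -0.23 with a batch term. That term assumes equal responses of the hairpin lines, so it cannot tell batch from a difference between those lines.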

How the results depend on the processing

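The GC corrections, the fits without the 3 GC-poor libraries and the block within each line were tests chosen only after the results were seen. Over the settings other than leaving out 1 library, 64 comparison counts moved by over 1.5 times and 115 did not. Of gene values there 14024 were as before, 649 lost their call, 443 gained one, 304 without a call moved by more than 1 SE and 27 reversed. Of list tests 3453 kept, 76 lost and 90 gained theirs. With 1 library left out in turn, 42 comparison counts moved and 102 did not. Of gene values then 10340 were as before, 766 lost their call, 61 gained one, 64 without a call moved and 1 reversed. For list tests these settings kept 2398, lost 41 and gained 45 calls or non-calls. Except where said, the cause was not tested.

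With only the groups compared fitted, the test called 1734 genes for activin B in control cells, 4501 in ALK7, 2166 in ALK7-DN, 3134 in sh2 and 1555 in sh1/2 cells, 0, 1, 0 and 45 (14 higher) for the interactions of ALK7, ALK7-DN, sh2 and sh1/2, and under DOX alone 159 (61 higher), 25 (6 higher), 863 and 2430 for ALK7, ALK7-DN, sh2 and sh1/2. For sh2 with activin B it called 440 (101 higher), and 698 genes were shared by the activin B contrasts. By construction this fit estimates the spread from fewer libraries.

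Without the low-count filter the interactions had 2 (ALK7), 1 (sh2) and 989 (sh1/2) calls, and ALK7 and ALK7-DN under DOX alone 186 and 91. DESeq2 called 33, 3 and 5 genes for the ALK7, ALK7-DN and sh2 interactions, and limma-trend on the deposited log2 values called 8 for ALK7.

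The replicate block called 27 genes in the ALK7 interaction, 4704 in that of sh1/2 and 529 in ALK7 under DOX alone. It ended the call of Pgk1-rs7 in the sh1/2 interaction (4.45) and changed no other call of a named gene from called to not called. For sh2 not every pair correlated over 0.1 (0.25, 0.0749 and 0.29), yet 6 of 6 libraries correlated best with their own number, so whether the numbers pair them stays open. The block within each line called 205 (ALK7), 1 (ALK7-DN) and 5956 (sh1/2) in the interactions. It ended the calls of the BMP list in ALK7 cells (0.0821) and in the sh1/2 interaction (0.0538), and of Rpl31-ps8 (1.48) and Krt7 (-0.31) in the latter. With the GC correction as well, activin B called 5250, 6082, 4527 and 5449 genes in control, ALK7, ALK7-DN and sh2 cells, the interactions of ALK7, ALK7-DN and sh2 469, 2 and 13, and 2074 genes were shared by the activin B contrasts.

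The batch term from the knock-down lines called 4096 genes for activin B in ALK7-DN cells, 5 in its interaction and 2789 for sh2 under DOX alone (1454 higher, against 524 of 1561). By construction it gives sh2 the contrasts of sh1/2, 5723 for activin B and 2768 for the interaction. With it, in sh2 cells activin B values reversed for Acvr2a (-0.28), Tgfbr1 (-0.32), Acvr2b (0.68), Ttr (0.0740), Bhlha15 (0.15), Col6a3 (0.0830), Col4a1 (0.0224), Tk1 (0.0377), Ccnd3 (0.15), Cpt1a (-0.0949), Aldoa (0.0467) and Mdm4 (-0.34). In the sh2 interaction Acvr2a (-0.43), Tgfbr1 (-0.44) and Mdm4 (-0.44) reversed. Under DOX alone Smad9 (0.26), S100a4 (0.28), Hsd17b7 (0.0578), Cpt1a (0.24) and Tpi1 (-0.0757) reversed in sh2.

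The GC correction called 32 genes in the ALK7 interaction, 961 (353 higher) in that of sh1/2, 786, 273 and 2591 for ALK7, ALK7-DN and sh2 under DOX alone and 2381 for sh2 with activin B. With GC and length corrected these were 55, 1293, 1024, 346, 2745 (1311 higher) and 2712, with 8 in the sh2 interaction, 3850 for activin B in ALK7-DN cells and 1886 shared genes. Aldoa reversed in the sh1/2 interaction (-0.0357 with GC, -0.0177 with GC and length, -0.0355 with GC and the block).

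Without the 3 GC-poor libraries activin B called 1476 genes in sh1/2 cells, the interactions of ALK7, sh2 and sh1/2 10, 1 and 64 (23 higher), and ALK7, ALK7-DN, sh2 and sh1/2 under DOX alone 623, 271, 2376 and 3351. Acvr2a (0.0599) and Rb1 (0.0282) reversed for activin B in sh1/2 cells, and Birc2 (0.0219) and Cdkn1b (0.000107) in the interaction. That fit has 1 library in the sh1/2 DOX arm. Of the 53 list calls, 14 held with an estimated correlation.

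Other list calls also ended with a setting. For activin B these were the BMP (0.127) and matrix lists (0.0635) in ALK7 cells with the GC correction and the block, the BMP list there with GC and length (0.0757), and the G1/S list in sh2 cells in DESeq2 (0.0724). In the interactions they were the unfolded protein response list of ALK7 in limma-trend (0.0834) and, for ALK7-DN, the secretory granule, islet hormone and cholesterol lists without the low-count filter (0.0633 each), the granule list without the 3 GC-poor libraries (0.0894) and the epithelial-mesenchymal transition list with only the groups compared (0.0940) and in limma-trend (0.386). Under DOX alone they were the BMP list of ALK7 with only the groups compared (0.0538) and the epithelial-mesenchymal transition list of sh1/2 without the filter (0.0627) and without the 3 GC-poor libraries (0.0833). With activin B the G1/S list of sh2 ended with only the groups compared (0.0515) and in limma-trend (0.0596).

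Leaving out 1 library gave, from lowest to highest, for activin B 2432 to 3031 calls (control), 3176 to 3597 (ALK7), 1917 to 2108 (ALK7-DN), 2297 to 3114 (sh2) and 2974 (without sh1/2 DOX 3) to 8227 (without sh1/2 DOX 2) in sh1/2 cells, with 3055 without sh1/2 DOX 1. For the interactions it gave 1 to 21 (ALK7), 0 to 0 (ALK7-DN, where edgeR called 0 with 342 at an unadjusted p under 0.05 and DESeq2 3), 1 to 2 (sh2) and 289 to 6983 (sh1/2). Under DOX alone it gave 151 to 226 (ALK7), 67 to 88 (ALK7-DN), 1055 to 1573 (sh2) and 4338 to 7912 (sh1/2), for sh2 with activin B 1016 to 1401, for list calls 49 to 60, and for Acvr1c in sh1/2 under DOX alone -1.64 to -1.46. Pgk1-rs7 reversed in the sh1/2 interaction without control DOX 1 (-0.11) and stood at 5.63 without control DOX 3.

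Depth limits low values, such as that of Prr5l at 0.159 CPM under DOX alone in control cells, more than those of abundant genes. The effect of depth was not tested.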

Other observations

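The tests of response size were chosen only after the results were seen.

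In control cells activin B also moved genes of other processes. Among p53 targets Btg2 (1.02 ± 0.06 SE) and Trp53inp1 (1.20 ± 0.11) rose and Perp (-1.10 ± 0.08) fell. Of the other genes, Krt7 rose by 1.79 ± 0.08, the lipase Mgll by 2.87 ± 0.34, the carnitine transferase Cpt1a by 0.68 ± 0.05 and Acly by 0.70 ± 0.05, while the phosphodiesterase Pde10a fell by 1.08 ± 0.07 and cyclin Ccnd2 by 1.21 ± 0.21. Gapdh stood at -1.05 ± 0.44 (adjusted p = 0.102), and it may share reads with pseudogenes.

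The 10 splits of 6 libraries are too few for a share under 0.05. For activin B, 1 of 10 splits, the real one, gave as many calls in every line, with 3180, 3953, 2515, 3070 and 5723 calls in control, ALK7, ALK7-DN, sh2 and sh1/2 cells against 0, 0, 0, 1 and 3792 in the highest other split. The split with 3792 put sh1/2 DOX 1 and 3, the GC-poor libraries, together with sh1/2 activin B 1. Between lines under DOX alone the number was also 1 of 10, with 310, 151, 1561 and 5934 calls for ALK7, ALK7-DN, sh2 and sh1/2 against 1, 1, 0 and 3332. The split with 3332 again put sh1/2 DOX 1 and 3 together. For sh2 with activin B the counts were 1443 and 0, also 1 of 10.

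The size of the activin B response, after GC correction and over genes called the same way in the 3 lines not compared, was 75.3% of that of control cells in sh1/2 cells (96 genes higher and 48 lower, adjusted permutation p = 0.01) and 88.8% in ALK7-DN cells (adjusted p = 0.01). It was 103% in ALK7 cells (adjusted p = 0.227) and 98.0% in sh2 cells (adjusted p = 0.43). The unadjusted p of 0.005 in sh1/2 and ALK7-DN cells is the smallest that 400 relabellings can give. Without the GC correction sh1/2 stood at 77.1% with all libraries. Also uncorrected, but without the 3 GC-poor libraries, it stood at 77.5%, with 1 library left in its DOX arm. The gene set differed by line, with 78 genes higher and 36 lower for sh2, so the percentages are not strictly comparable between lines. A lower response with less Acvr1c is a candidate explanation in sh1/2 cells, yet sh2 cells, also low in Acvr1c, stood at 98.0% over their own gene set. In sh2 and ALK7-DN cells batch and treatment coincide, so their values do not decide this.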
